A study of Coprinopsis cinerea with 6 samples.

How the data were processed

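RNA from gill tissue of young fruiting bodies was sequenced by the authors in 6 libraries, 3 of the wild type and 3 of the SRR1 mutant. The extract protocol in the labels names a column-based RNA kit and an mRNA library kit. Reads were aligned with STAR 2.6.1, per the submitters' processing notes. The authors deposited 1 table of raw counts per gene model, made with featureCounts 2.0.1, per the file headers. The recorded command counted read pairs over coding exons, 1 transcript model per gene, with a minimum fragment length of 40 bp. It required both ends to be mapped, left out chimeric pairs, counted multi-mapping reads and gave no strand option. Reads that fit near-identical copies were therefore counted at more than 1 gene, and reads of overlapping genes on opposite strands were not told apart by strand. The command lists 7 alignment files and the table has 6 count columns; the additional entry is a second alignment file of wild type replicate 3, whose counts were not used here. The genome build is not given in the sources used here, so positions are given on the scaffolds as the table names them. All 13615 gene models have a coding length that is a multiple of 3, so the lengths exclude untranslated regions.

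Columns were assigned to samples by the sample descriptions, and groups were taken from the titles. The descriptions carry different codes in the 2 groups beyond the strain name, and what these codes mean is not given. The table held 13615 gene models, of which 761 had no read pair in any library. The default edgeR expression filter kept 11683 genes.

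The main test was edgeR 4.0.16 (quasi-likelihood, TMM factors, a design with genotype only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes; principal components and correlations use log2 CPM with a prior count of 2. The alternatives were DESeq2 1.42.0, RLE and upper quartile factors, library sizes alone, no filter, a filter of at least 5 CPM in at least 3 libraries, limma-voom (limma 3.58.1), robust estimation, a test against a log2 fold change of 1, the replicate number as a block and leaving out each library. All were chosen before the data were examined. Replicate numbers are shared between the groups in the titles, but the sample descriptions end in different numbers in the 2 groups. Nothing says that the replicate numbers pair the libraries.

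The deposited gene identifiers could not be paired with names: 0 of 13615 matched the 13657 genes of the reference table supplied, which is of the assembly CC3 and gives locus tags without product descriptions. For this reason the 28 functional gene lists and the test of product families that had been planned were not run, SRR1 itself was not identified among the models, and only 2 genes per direction are named. The rule was the largest absolute log2 fold change among genes past the threshold, with the groups fully separated and a mean of at least 10 CPM in the higher group. The absence of names led to the added descriptions by abundance, position and gene structure, which were chosen after the data were seen, except the test of neighbouring genes, which had been planned.

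Neighbouring called genes were counted in genome order over tested genes and compared with 100000 permutations of the calls. Runs were compared with 2000 permutations. Coding length and exon number were compared with 100000 permutations of the calls within 20 bins of mean log2 CPM, two-sided, over 8 tests. Shares per scaffold used Fisher's exact test on scaffolds with at least 100 tested genes, the rotation test of scaffolds compared the smallest one-sided hypergeometric p over 13 scaffolds, and the strand arrangement of neighbouring pairs used 6 Fisher's exact tests. An added alternative removed a smooth trend of each library's log2 CPM deviation with log2 coding length, as an offset. Python 3.11.15 with scipy 1.17.1 was used for these tests.

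At these library sizes 1 CPM stands for 18.3 to 24.4 counted read pairs before TMM scaling, so levels under 1 CPM rest on few pairs. The edgeR step was tested on simulated counts of the same 11683 genes, drawn from the means, library sizes and dispersions of this comparison with 100 genes changed by a log2 fold change of 1 and 100 by 2. It recovered 43% and 92% of these, with 16 false calls among 11483 unchanged genes. Set against the genes recovered, these false calls were a larger share of all calls than the adjusted threshold is meant to allow. DESeq2 recovered 58% and 92% in this simulation, with 31 false calls, again a larger share than the threshold is meant to allow. Both groups were given the same dispersions, and as many genes were raised as lowered. The simulation therefore did not test unequal spread of the groups or mostly one-sided changes. In a simulation with a length trend planted in wild type replicate 3, the length correction brought Spearman's rho of length with that library's deviation from -0.686 to -0.00408. The planted trend was stronger than that of the data (rho = -0.330) and lay in 1 library only. In the data, length also correlated with the log2 fold change (rho = -0.137), so the removal also takes out a group difference along length. The simulation did not test that case. The neighbour test gave a ratio of 1.02 for scattered calls and 11.4 for planted runs.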

Results

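Transcript levels were measured by RNA sequencing in gill tissue of young fruiting bodies of Coprinopsis cinerea, an ink cap mushroom used as a laboratory model of fruiting body development. Gills are the plates under the cap whose surface carries the basidia, the cells in which meiosis takes place and on which the spores form. The design had 2 groups, the wild type (n = 3 libraries) and a mutant of SRR1, a transcription factor that the series title connects with the shaping of spores (n = 3 libraries). The labels do not say what kind of mutation the strain carries. The comparison asks which genes are expressed differently in the gill when SRR1 is mutated. The counts of gene-assigned read pairs summed to 24373334, 19008671 and 18816585 in wild type replicates 1, 2 and 3 and to 18333896, 20014106 and 19306843 in mutant replicates 1, 2 and 3. The labels number the replicates but do not say that they came from separate fruiting bodies or cultures. The edgeR p-values below therefore measure differences against the spread between these libraries, which may be partly technical. The p-values of gene position and gene structure compare called genes with other genes and do not measure that spread.

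The 6 libraries separated by genotype. Over the 11683 tested genes, the first principal component of log2 CPM held 62.0% of the variance and placed the 3 wild type libraries on one side and the 3 mutant libraries on the other. The mutant libraries lay close together, with Spearman correlations between 0.989 and 0.991 within the group, whereas the wild type libraries correlated at 0.956 to 0.980. Pairs drawn from different groups correlated at 0.931 to 0.963. The biological coefficient of variation estimated by edgeR was 0.291 within the wild type and 0.154 within the mutant. The second component held 19.5% of the variance and spread the wild type libraries, with replicates 2 and 3 at opposite ends. A chi-square comparison of counts, which covers counting error only and served to look for a library held more than once, gave at least 25 per degree of freedom for every pair.

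**Figure D1:**
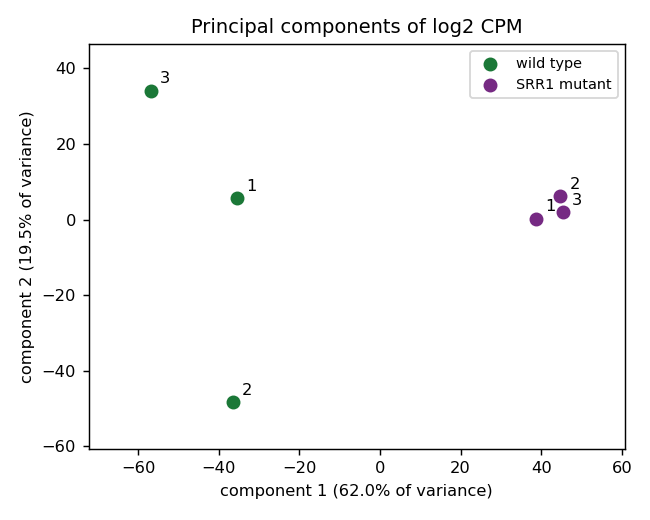
Principal components of log2 CPM over the tested genes. Each point is 1 library, numbered by its replicate; the x axis is component 1 (62.0% of the variance) and the y axis component 2 (19.5%). The wild type libraries lie apart from the mutant libraries on component 1 and are spread widely on component 2.

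More genes were lower than higher in the SRR1 mutant gill, and the lower genes differed by larger folds. Of 1197 genes past an adjusted p of 0.05, 817 were lower in the mutant than in the wild type and 380 were higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, two-sided, 3 libraries against 3). The strong changes were almost all losses: 276 genes were lower by at least 4-fold against 17 that were higher by as much, and 95 genes were lower by at least 16-fold against 3 that were higher. The number of genes higher by at least 16-fold depended on single libraries. It was 1 without mutant replicate 2, and 5 without mutant replicate 3 or without wild type replicate 2. The median log2 fold change of the lower genes was -1.40, with quartiles at -2.57 and -0.96, and that of the higher genes was 0.93, with quartiles at 0.78 and 1.19. Over all tested genes, called or not, 33.3% had each library of one group above each library of the other, where chance gives 10%.

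The balance of moderate changes depended on how the libraries were scaled. With library sizes alone, which put the median log2 fold change of all genes at 0.206 against 0.0140 with TMM factors, the calls split into 628 lower and 1041 higher genes. With upper quartile factors they split into 707 and 667. The strong losses were less affected: 242 genes were lower by at least 4-fold with library sizes alone, against 33 that were higher. Lower genes outnumbered higher ones without each of the 6 libraries in turn, but the counts moved. Without mutant replicates 1, 2 and 3 in turn, 516, 480 and 489 genes were lower and 96, 53 and 64 higher. Without wild type replicates 1 and 2 in turn, 657 and 1157 genes were lower and 217 and 739 higher.

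**Figure D2:**
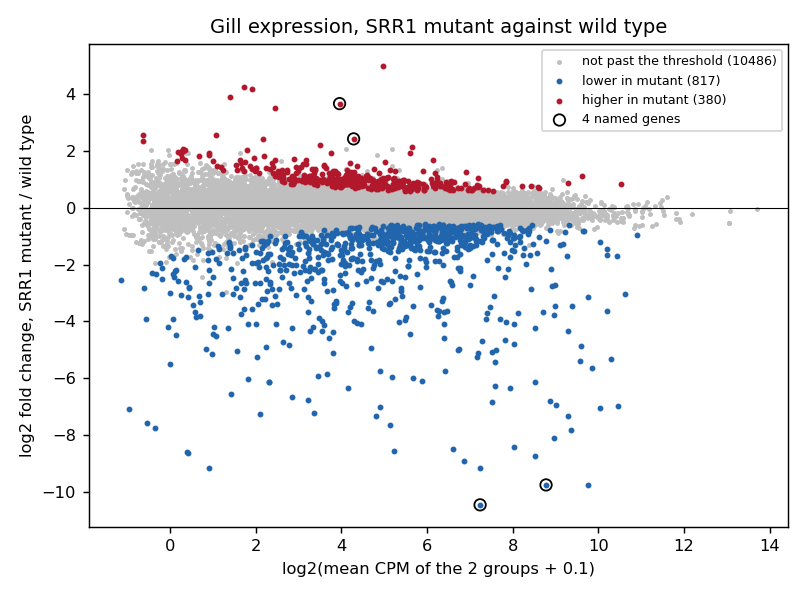
Log2 fold change of the SRR1 mutant over the wild type (y axis) against the log2 of the mean CPM of both groups (x axis), 1 point per tested gene. Blue points are the 817 lower genes, red points the 380 higher genes and circles the 4 named genes. The losses reach much larger sizes than the gains, also among abundant genes.

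The gene identifiers are not paired with names here, so 2 genes per direction are given by the rule for named genes. The largest loss under that rule was of CopciAB_381084.T0, a gene of 5 coding exons and 603 coding bp on the plus strand of scaffold_11 from 2085536 to 2086763. Its level was 301.4 ± 219.2 CPM (SD, n = 3) in the wild type and 0.207 ± 0.191 CPM in the mutant (log2 fold change -10.44 ± 0.80 SE, edgeR adjusted p = 1.54e-05). The mutant libraries held 3, 9 and 1 read pairs of this gene, and the wild type libraries 6256, 1841 and 8880. The size of this fold depended on single libraries, with a log2 fold change of -11.50 without mutant replicate 2 and -9.74 without wild type replicate 3. The next was CopciAB_462515.T0, with 2 coding exons and 639 coding bp on the minus strand of scaffold_2 from 3768017 to 3768718. It fell from 876.6 ± 448.1 CPM in the wild type to 1.01 ± 0.35 CPM in the mutant (log2 fold change -9.74 ± 0.49 SE, edgeR adjusted p = 8.79e-07).

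The strongest gain under the same rule was of CopciAB_367424.T0, with 5 coding exons and 2280 coding bp on the minus strand of scaffold_1 from 957081 to 959565. It rose from 2.26 ± 0.03 CPM in the wild type to 28.6 ± 14.7 CPM in the mutant (log2 fold change 3.65 ± 0.42 SE, edgeR adjusted p = 0.000326). A gene model with the same lengths of all 5 coding exons lies on scaffold_2 from 58183 to 60667, and multi-mapping reads were counted, so the values of both models are uncertain. CopciAB_405665.T0, a gene with 1 coding exon of 1986 bp on the minus strand of scaffold_1 from 974108 to 976093, rose from 6.09 ± 2.20 to 32.7 ± 2.5 CPM (log2 fold change 2.42 ± 0.28 SE, edgeR adjusted p = 0.000286). These 4 genes kept their direction and stayed past the threshold in all 16 alternative analyses that were checked for them. The test against a log2 fold change of 1 was not among these.

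The strongly reduced genes included some of the abundant transcripts of the wild type gill. Of the 95 genes lower by at least 16-fold, 70 had a wild type mean of at least 10 CPM, 42 of at least 100 CPM and 11 of at least 1000 CPM. The 3 most abundant, singled out after their values were seen, are given by position. The gene on scaffold_7 from 1444856 to 1445775 had 2777 ± 1859 CPM (SD, n = 3) in the wild type and 22.3 ± 5.2 CPM in the mutant. The gene on scaffold_1 from 2986769 to 2989543 had 2459 ± 175 CPM in the wild type and 61.2 ± 1.7 CPM in the mutant. The gene on scaffold_4 from 1110591 to 1113617 had 2091 ± 1267 CPM in the wild type and 15.96 ± 1.66 CPM in the mutant. Their log2 fold changes were -6.96 ± 0.53, -5.33 ± 0.22 and -7.03 ± 0.48 (SE). Without wild type replicate 3 they were -6.29, -5.36 and -6.45. Among all lower genes, 21 were nearly silent in the mutant, with a mean under 1 CPM there and at least 10 CPM in the wild type. CopciAB_381084.T0 had the highest wild type mean of these, with uneven levels of 270, 99.4 and 534 CPM in wild type replicates 1, 2 and 3. No gene met the reverse condition, a mean under 1 CPM in the wild type and at least 10 CPM in the mutant. Among the genes higher by at least 2-fold the median mutant level was 13.2 CPM, and the highest was 1067 CPM.

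As a share of all gene-assigned read pairs, the 817 lower genes made up 11.4% ± 2.3 (SD, n = 3) of the wild type libraries and 3.82% ± 0.15 of the mutant libraries. The 95 genes lower by at least 16-fold made up 2.98% ± 1.45 in the wild type and 0.0644% ± 0.0007 in the mutant. The 380 higher genes made up 1.09% ± 0.12 in the wild type and 2.26% ± 0.15 in the mutant. The 2 groups did not overlap in any of these shares (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows), and the sets were chosen on the same libraries, so the shares are not independent evidence of direction.

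**Figure D3:**
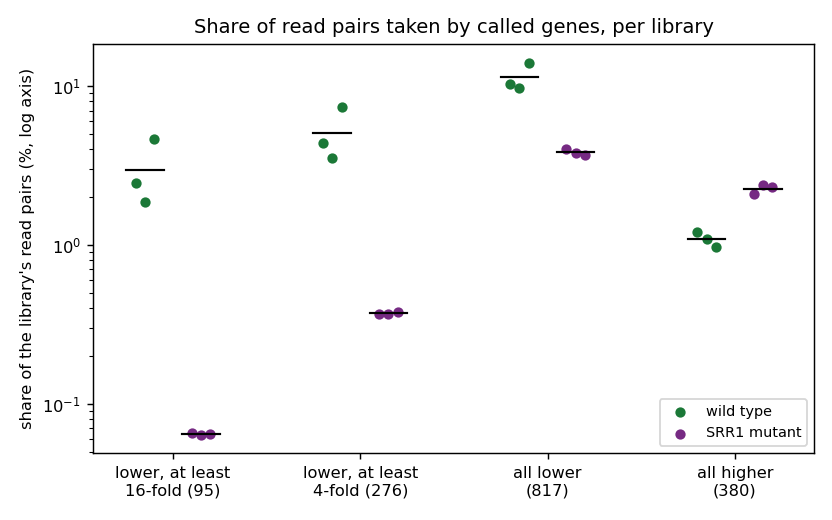
Share of each library's gene-assigned read pairs (%, log axis) taken by 4 sets of called genes, with the number of genes in parentheses. Each point is 1 library, green for wild type and purple for the SRR1 mutant, and the black line is the group mean. The 95 genes lower by at least 16-fold take 1.85% to 4.62% of the wild type libraries and 0.0637% to 0.0651% of the mutant libraries.

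The wild type libraries differed in how strongly they expressed the genes that were lower in the mutant. Replicate 3 was the highest of the 3 in 537 of the 817 lower genes (65.7%), compared with 34.8% of the uncalled genes. The lower genes made up 14.1% of the read pairs of wild type replicate 3, 10.3% of replicate 1 and 9.75% of replicate 2. Without replicate 3, 834 genes were lower and 314 higher, and 693 of the 817 lower genes were called again. The libraries also differed with gene length. Spearman's rho across genes of coding length with a library's deviation from the mean of all libraries was 0.198, 0.241 and -0.178 in wild type replicates 1, 2 and 3 and -0.0298, -0.154 and -0.160 in mutant replicates 1, 2 and 3. Genes are not independent replicates, so these values describe the libraries.

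Genes that were lower in the mutant lay next to each other in the genome more often than chance. Of 11665 pairs of neighbouring tested genes, 89 pairs were both lower, where permuting the calls gave 57.0 on average (ratio 1.56, one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). For genes lower by at least 2-fold the ratio was 2.01, with 59 pairs against 29.3. Higher genes were neighbours in 21 pairs against 12.3 by chance (ratio 1.70, one-sided permutation p = 0.0123), and those higher by at least 2-fold in 7 pairs against 1.99 (ratio 3.51, one-sided permutation p = 0.00377). Without pairs that overlap or lie within 500 bp of each other the excess of all higher genes missed the threshold (ratio 1.64, one-sided permutation p = 0.0764). Part of these pairs lie among 4 models on scaffold_1 and scaffold_2 that share exon lengths. With the models on scaffold_2 left out, so that each was counted once, both excesses passed the threshold. There were 20 pairs of higher genes (ratio 1.64, one-sided permutation p = 0.0201) and 6 of those higher by at least 2-fold (ratio 3.09, one-sided permutation p = 0.0136). Without all 4 models neither excess passed. There were 18 pairs of higher genes against 12.04 (one-sided permutation p = 0.0578) and 4 pairs of those higher by at least 2-fold against 1.88 (one-sided permutation p = 0.121). Of the 89 lower pairs, 60.7% had both genes on the same strand, compared with 47.6% of the other neighbouring pairs (two-sided Fisher's exact test, adjusted p = 0.0429 over 6 tests). Convergent pairs were 13.5% of the lower pairs and 26.2% of the others (two-sided Fisher's exact test, adjusted p = 0.0307). Both tests of strand arrangement take pairs as independent, although pairs within a run share a gene.

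Lower genes formed 8 uninterrupted runs of 3 genes, where permuted calls gave 3.72 runs of at least 3 genes on average (one-sided permutation p = 0.0435). The run with the strongest losses throughout spanned scaffold_8 from 810877 to 813164, where all 3 genes lay on the plus strand with log2 fold changes between -4.96 and -3.39. Another run, on scaffold_2 from 3903334 to 3905919, had log2 fold changes between -3.67 and -3.10, again with all 3 genes on the plus strand. A further run on scaffold_8, from 760596 to 767845, held 1 gene with a log2 fold change of -6.02 and 2 genes with log2 fold changes of -0.94 and -0.93. Among scaffolds, scaffold_8 had the highest share of lower genes. There, 77 of 676 tested genes were lower (11.4%), compared with 6.72% elsewhere (two-sided Fisher's exact test, adjusted p = 0.000468 over 28 tests). That test takes neighbouring genes as independent. When the calls were rotated along the genome, keeping their order, and the most enriched of 13 scaffolds was taken anew in each rotation, 3426 of 11682 rotations gave an enrichment at least as strong (one-sided rotation permutation p = 0.293), so the excess on scaffold_8 did not hold up in that test. Genes within 100 kb of the outermost gene of a scaffold were not enriched past the threshold (7.77% lower, compared with 6.97% elsewhere, adjusted p = 0.837).

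The higher genes included 1 group of 3 consecutive tested genes on scaffold_1 between 957081 and 976093, with log2 fold changes from 2.42 to 4.24. It holds both named higher genes and a model between them from 960158 to 961584. A pair of models on scaffold_2, from 56170 to 57535 and from 58183 to 60667, rose by log2 fold changes of 3.90 and 3.51. A second run of higher genes, on scaffold_4 from 3138097 to 3151380, held 4 genes with log2 fold changes between 0.71 and 1.28. These 2 runs of at least 3 higher genes, against 0.4 on average with permuted calls, missed the threshold (one-sided permutation p = 0.0610).

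**Figure D4:**
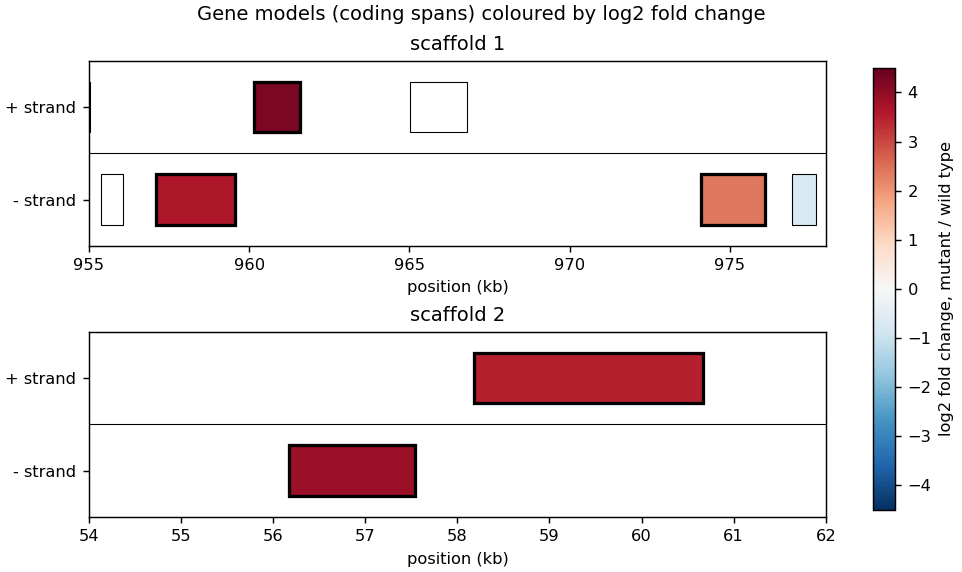
Gene models on scaffold_1 (upper panel) and scaffold_2 (lower panel), drawn to scale by the span of their coding exons and by strand, with position in kb on the x axis. Colour gives the log2 fold change of the mutant over the wild type, thick outlines mark genes past the threshold and white boxes were not tested. The 3 higher genes on scaffold_1 and the 2 on scaffold_2 have log2 fold changes from 2.42 to 4.24.

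The lower genes had a median coding length of 1443 bp and the uncalled genes one of 1159.5 bp. Against genes of like abundance the geometric mean length of the lower genes was 1.18 times that expected (permutation adjusted p = 8e-05 over 8 tests). Coding length also moved with the libraries, and after the trend with length was removed from each library the ratio was 1.07 (adjusted p = 0.0066). The higher genes had a median coding length of 1093.5 bp and a ratio of 0.937 (adjusted p = 0.0921). With DESeq2 calls the ratio was 0.926 and passed the threshold (adjusted p = 0.00904), and after the trend was removed it was 1.14, in the opposite direction (adjusted p = 8e-05). Genes of at most 300 coding bp were 4.65% of the lower and 7.58% of the uncalled genes (adjusted p = 0.0129), a difference that missed the threshold after the trend was removed (adjusted p = 0.188). The geometric mean number of coding exons was 0.940 times that expected in the lower genes (adjusted p = 0.0243) and 1.12 times in the higher genes (adjusted p = 0.00648). Neither passed when the calls were permuted without regard to abundance (adjusted p = 0.109 and 0.0633) or for calls of at least 2-fold (adjusted p = 0.734 and 0.646), and both passed after the trend was removed (adjusted p = 0.000107 and 8e-05). Single-exon genes were 9.79% of the lower, 8.42% of the higher and 10.6% of the uncalled genes. Neither difference passed the threshold (adjusted p = 0.708 and 0.216), although that of the higher genes did after the trend was removed (adjusted p = 0.0340).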

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

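The settings that removed the coding length trend, left out neighbouring pairs or models, or changed how calls were permuted, and all settings of gene structure and of scaffold_8, were chosen after the data were seen. Lower genes numbered 628 to 1089 under the alternatives that used all 6 libraries, except 259 in the test against a log2 fold change of 1, and 480 to 1157 with 1 library left out. Apart from that test, genes lower by at least 2-fold numbered 470 to 645 and, with 1 library left out, 467 to 697. Higher genes numbered 586 with DESeq2, 667 with upper quartile factors, 1041 with library sizes only, 9 in the test against a log2 fold change of 1, and 53 to 739 with 1 library left out. Those higher by at least 2-fold numbered 255 with upper quartile factors, 400 with library sizes only and 49 to 216 with 1 library left out. Those higher by at least 4-fold numbered 11 with DESeq2, 27 with upper quartile factors, 33 with library sizes only, 5 with the stricter filter and 10 to 19 with 1 library left out. Those higher by at least 16-fold numbered 0 with the stricter filter, 1 each with limma-voom, robust estimation and the replicate block, and 1 to 5 with 1 library left out. Upper quartile factors and library sizes only put the median log2 fold change of all genes at 0.116 and 0.206, against 0.0140 with TMM factors. The test against a log2 fold change of 1 passes fewer genes by construction, and the stricter filter tested 9426 genes; the cause of the other moves was not tested. With the replicate block, 703 genes were lower and 225 higher. The replicate numbers showed no sign of pairing the libraries: deviations of same-numbered libraries correlated at 0.0785, -0.0530 and -0.0368 across genes. Only wild type replicate 1 correlated best with its own number. Correlations over all pairs were weak, from -0.0828 to 0.117, so they cannot exclude shared days or batches. Near-silent genes numbered 16 to 28 over the alternatives. The ratio of neighbouring higher genes was 1.64 without pairs that overlap or lie within 500 bp and missed the threshold, with fewer pairs available. With the copied models counted once the ratio was 1.64, and 3.09 for genes higher by at least 2-fold, and both passed the threshold. Without all 4 copied models it was 1.495, and 2.12 for genes higher by at least 2-fold, and both missed the threshold. The coding length of the higher genes reversed after the length trend was removed, from a log2 difference of -0.0934 to 0.19; the removal acts on length itself. The gene lists, the product families and the neighbour test without pairs of the same product were not run, since the identifiers were not paired with products. Depth limits levels under 1 CPM.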

Other observations

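Of the tests below, those of the strong losses against scaling, of uneven progress, of the removed length trend and of neighbouring pairs left out or permuted within abundance bins were chosen after the data were seen.

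The 2 groups of higher genes on scaffold_1 and scaffold_2 share exon lengths; their sequences were not compared. The models on scaffold_1 from 957081 to 959565 and on scaffold_2 from 58183 to 60667 have the same lengths of all 5 coding exons. Their neighbours, from 960158 to 961584 and from 56170 to 57535, have 6 coding exons each, of which 5 have equal lengths. Both models lie on opposite strands in the 2 places and in inverted order. The neighbours had the same counts in the wild type libraries, 3, 10 and 5 read pairs at each place, and 139, 186 and 49 against 108, 147 and 40 in the mutant libraries. Multi-mapping reads were counted, so a read pair can be counted at both places, and the 4 models are not shown to be 4 separate gains. Mutant replicate 3 was the lowest of the mutant libraries in each of the 4 models, with 240 read pairs of the first model against 702 and 817 in replicates 1 and 2. The higher gene with the largest fitted fold, on scaffold_3 from 3283319 to 3283733 and singled out after its values were seen, had uneven mutant libraries of 35, 3464 and 350 read pairs.

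Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 1197 genes and the highest other gave 0, so 1 split reached the real count, but 10 splits are too few for a share under 0.05.

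The lower genes outnumbered the higher ones. Scaling of the libraries stays open for the balance among moderate changes, since the lower share of calls of at least 2-fold fell to 54.0% with library sizes only, against 79.3% with TMM factors. For the strong losses, the lower share of calls of at least 4-fold was at least 88% over the 4 other scalings. These scalings put the median log2 fold change between -0.0155 and 0.206, a small range beside a log2 fold change of 2. The strong losses thus did not depend on the choice among these scalings, but a larger scaling error was not tested. The tables argue against a single library, since the lower share of calls of at least 2-fold was at least 76.3% without each library in turn. A hypothesis that stays open is that the mutation of SRR1 lowers these genes in the gill. The design confounds it with any other difference between the groups, such as developmental stage at sampling, which was not tested.

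Wild type replicate 3 had the highest level in most of the lower genes. Its deviation from the other wild type libraries followed coding length (Spearman's rho = -0.330 across genes), past the bound set for RNA quality acting through length. Against the mean of all libraries, replicate 3 (-0.178) lay near mutant replicates 2 and 3 (-0.154 and -0.160). Wild type replicates 1 and 2 lay apart (0.198 and 0.241). Within the wild type the trend therefore set replicate 3 apart, although it did not among all 6 libraries. RNA quality acting through length thus stays open for the deviation of replicate 3. The share of lower genes highest in replicate 3 was 65.7% before the trend was removed and 73.3% after. The removal did not lower it, which argues against the trend as the whole cause. Before the removal the share was 77.5% below the median coding length and 58.3% at or above it. Another hypothesis that stays open is uneven progress of the wild type samples along the changes that separate the groups. Across genes, the difference of wild type replicates 3 and 2 correlated with the difference of the mutant and wild type replicate 1 at r = -0.215, and with replicates 1 and 2 exchanged at r = -0.108, a weak relation just past a bound of -0.1 set afterwards. The difference of wild type replicates 1 and 2 gave r = -0.132 with that of the mutant and replicate 3, so the relation was not particular to replicate 3, and genes are not independent replicates.

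Lower genes lay side by side more often than chance. Without pairs that overlap or lie within 500 bp, 42 lower pairs remained against 31.1 expected (ratio 1.35, one-sided permutation p = 0.0305). With all pairs there were 89 against 57.0. This argues against reads shared by touching gene models as the whole cause. More of the excess lay in the pairs left out, so such reads stay open as a part of it. Against reads shared by near-identical copies, the ratio was 1.51 without pairs whose coding lengths differ by at most 5%, although copies of unlike length escape this test. Against neighbours of like abundance, the ratio was 1.56 with calls permuted within abundance bins. Shared regulation of neighbours, which was not tested, also stays open as a hypothesis. So do tandem copies of unlike length, since no sequences were compared.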
